A study of Rattus norvegicus with 8 samples.

How the data were processed

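RNA was measured in prefrontal cortex punches from 8 male Sprague Dawley rats, 1 rat per library, aged 3 to 5 weeks. The labels put 4 libraries in a control group and 4 in a stress group, and each group holds replicate numbers 1 to 4. Per the labels' protocols, 100 ng of total RNA was depleted of ribosomal RNA, made into strand-specific libraries and amplified over 11 PCR cycles. The stress schedule in the labels gave 2 stressors a day, drawn from restraint for 4 h, a forced swim of 5 min in water at 15 °C, 30 min on an elevated platform, and 1 h in a tilted wet cage on a shaker. The same schedule text accompanies the control libraries, so the group was taken from each library's source name. How many days the schedule ran is not given in the sources used here.

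The deposited files hold raw read counts per Ensembl gene ID, 1 file per library, with no pooling of libraries. Per the submitters' processing notes, bcl2fastq 1.8.4, HISAT2, featureCounts 1.5.0-p3, edgeR 3.20.9 and the rat build rn6 were used. The HISAT2 version, the annotation release, the strand setting and the handling of reads that map to several places are not given in the sources used here. Each file lists the same 32883 gene IDs, all of which name a gene, so no summary row had to be set aside. Of these, 8840 had no read in any library. Genes that share reads with a near-identical copy or with an overlapping gene can therefore not be set apart from others.

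The files do not pair the IDs with gene names, and the reference table at hand matched 0 of the IDs to a symbol. Results are therefore given by ID, with 2 IDs that were higher and 2 that were lower under stress. For the same reason the 3 DNA methyltransferase genes that were to be named and the 39 gene lists fixed in advance (synaptic, stress-hormone, immediate early, metabolic and cell type lists) were not analysed here, and markers of other tissues in the punch were not used. No genome sequence or positions were used, so gene length and GC content were not examined.

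Counts were filtered with filterByExpr of edgeR at its defaults (minimum count 10, minimum total 15), which kept 16760 genes holding 99.967% of all counts, and were scaled with TMM factors. Stress was compared with control by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with group as the only term and all 8 libraries in the fit. The p-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are printed as CPM (counts relative to the library total) on TMM-scaled library sizes, as mean ± SD over 4 rats. The standard error of a log2 fold change is the fold change divided by the square root of F. Differences of a single measure between groups were tested with an exact two-sided permutation test over all assignments of 4 and 4 libraries, whose smallest possible p is 0.02857. Principal components were computed from log2 CPM of the tested genes. The share of genes with no difference was estimated from the density of p-values above 0.5.

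The rule for printed IDs, fixed before the data were examined, took genes with a mean log2 CPM of at least 1 that passed the threshold with no overlap between the groups, in order of fold change. Where too few passed in a direction, it took the genes with the smallest unadjusted p. The rule asked for genes with a symbol, up to 10 per direction, and it was applied to IDs and limited to 2 per direction. The groups, the test, the threshold and most alternatives were also fixed before the data were examined. These alternatives were 3 other scalings, 2 other filters, DESeq2 1.42.0, limma 3.58.1 with voom (with and without quality weights), the edgeR likelihood ratio test and its robust fit, a replicate block, 1 surrogate variable from sva 3.50.0, other thresholds, and leaving out each library in turn. Thinning of all libraries to the smallest total, the newer quasi-likelihood estimate, removal of the 10 most abundant IDs and an adjusted p under 0.06 were chosen after seeing the data.

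The test was tested on simulated data made from the means, dispersions and library sizes of the 16760 genes of this comparison, with 200 genes changed. It recovered 24% of genes changed 1.25-fold, 66% of those changed 1.5-fold, 80% of those changed 2-fold and 94% of those changed 3-fold, with 4.35% false calls. In the same simulated counts 6.47% of the calls of limma-voom and 19.7% of those of DESeq2 were false. The simulated genes varied independently of each other, unlike real genes, and only 200 of them changed. The shares recovered and the shares of false calls therefore cannot be carried over to the real comparison. There, 461 genes at an unadjusted p under 0.05 differed by 1.5-fold or more, and 2 genes passed the adjusted threshold. Total counts ran from 42195741 to 66854820 per library, the biological coefficient of variation was 10.1%, and the median standard error of a log2 fold change was 0.087. Reads carry no molecular identifiers in the labels, so depth speaks for counting error only.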

Results

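Bulk sequencing of RNA depleted of ribosomal RNA was used to compare the prefrontal cortex of juvenile to adolescent male rats after prolonged unpredictable stress with that of control rats. The series title sets this comparison within a study of DNA methyltransferase 3A, an enzyme that places new methyl groups on DNA, and of lasting effects of stress on synapses and behaviour. The data hold 4 control and 4 stress libraries, each from a different rat. Counts assigned to genes totalled 42722654, 49622782, 43932262 and 42195741 in control replicates 1 to 4, and 66854820, 59509323, 62332981 and 55037169 in stress replicates 1 to 4. The mean total was 44618400 ± 3414560 counts in control and 60933600 ± 4960360 in stress libraries (SD, n = 4 each, exact permutation p = 0.0286, adjusted p over 8 sample measures = 0.0457). The deepest control library was therefore shallower than the shallowest stress library. The labels record no sequencing date or batch, so any batch that followed depth cannot be told apart from the groups.

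Spearman correlations of log2 CPM ran from 0.995 to 0.997 among the 6 control pairs, from 0.993 to 0.998 among the 6 stress pairs, and from 0.986 to 0.997 among the 16 pairs across groups. No pair of libraries agreed within counting noise, with a chi-square of 14.48 to 136.8 per degree of freedom over the 28 pairs. Stress replicate 2 stood furthest from the controls, with correlations of 0.986 to 0.992 and a chi-square of 63.67 to 136.8 per degree of freedom, and it correlated with the other stress libraries at 0.993 to 0.995. Stress replicate 3 correlated with the controls at 0.9957 to 0.9964, and with stress replicates 1, 2 and 4 at 0.9976, 0.9928 and 0.9966. The most abundant gene ID took 4.39 ± 0.335% of the counts in control and 3.72 ± 0.530% in stress libraries (SD, n = 4 each, exact permutation p = 0.0857, adjusted p over 8 sample measures = 0.114).

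Along the first principal component, which held 36.6% of the variance, the groups did not overlap. Scores averaged -14.8 ± 10.3 in control and 14.8 ± 17.9 in stress libraries (SD, n = 4 each), a difference of 29.6 (exact permutation p = 0.0286, the smallest this design allows, adjusted p over 8 sample measures = 0.0457). The separation was narrow, since control replicate 4 scored -2.93 and stress replicate 3 scored -0.95. Both groups were spread along this component, from -28.0 in control replicate 3 to 39.5 in stress replicate 2. Without stress replicate 2 the difference was 23.7 (exact permutation p = 0.0857). Without any 1 of the 4 control libraries it was 30.8 to 35.02 (exact permutation p = 0.0571). Without stress replicate 1, 3 or 4 it was 33.7, 35.4 and 29.6 (exact permutation p = 0.0286 each). The second component, with 14.9% of the variance, did not separate the groups (5.57 ± 17.7 in control and -5.57 ± 3.94 in stress libraries, SD, n = 4 each, exact permutation p = 0.257, adjusted p = 0.257).

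**Figure D1:**
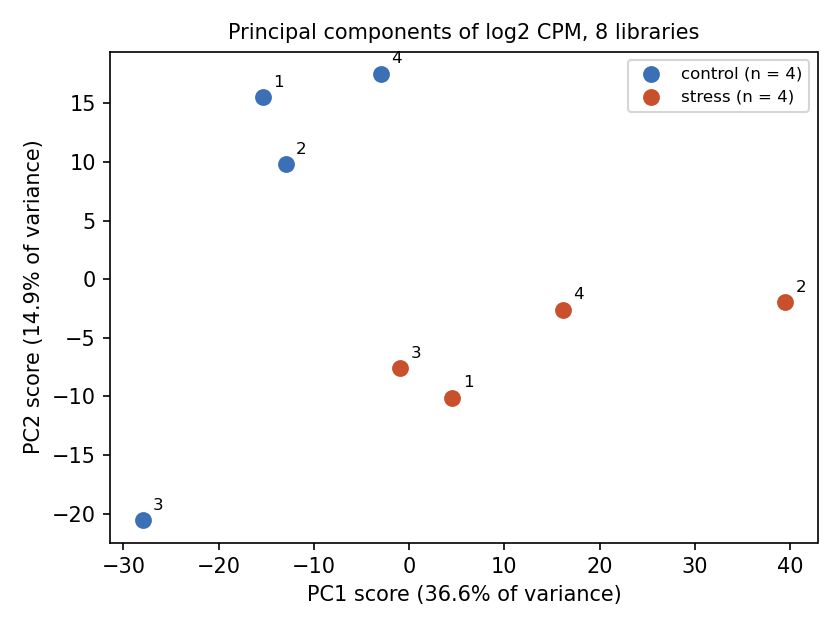
Scores of the 8 libraries on the first and second principal components of log2 CPM, with the share of variance on each axis. Blue points are control and orange points stress libraries, numbered by replicate. The 4 control libraries lie at or below -2.93 on the first component and the 4 stress libraries at or above -0.95.

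Between the stress and control libraries, small shifts were seen in a large part of the measured genes. A batch that followed depth could not be told apart from stress here, and chance was not excluded. Of 16760 genes tested, 4939 (29.5%) had an unadjusted p under 0.05 in the edgeR quasi-likelihood test, against 838 expected if no gene differed. Of these, 2611 were higher and 2328 lower under stress. Their median change was 1.19-fold, and 90% of them changed by 1.48-fold or less. A total of 2940 genes (17.5%) had no overlap in CPM between the 4 control and the 4 stress rats, where chance gives 2.86% on average over splits. Of them, 1381 were higher and 1559 lower under stress. Genes that vary together can move this share far from 2.86% in a single split, and it was not examined for other splits. From the density of large p-values, 52.1% of the tested genes were estimated to differ between the groups, an estimate that takes genes as independent. The same formula gave 50.1% for the other split of the 8 libraries with the most genes at an unadjusted p under 0.05, which exchanges control replicate 4 with stress replicate 3.

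Few single genes could be named with confidence among these. Only 2 genes passed the adjusted threshold of 0.05 in the edgeR quasi-likelihood test, both lower under stress, and none was higher. The adjusted p-values lay close together just above the threshold. The count was 27 at an adjusted p under 0.06 and 2349 at an adjusted p under 0.1, where 1314 genes were higher and 1035 lower. The count depended on the test. DESeq2 called 2075 genes (1160 higher and 915 lower), the edgeR likelihood ratio test 1628, limma-voom with quality weights 404, and limma-voom without weights 2. Within the edgeR quasi-likelihood test it depended on the filter, the scaling and the terms of the model. It was 99 with no filter (61 higher and 38 lower) and 697 with a replicate block (481 higher and 216 lower). It was 0 on scaling by library size only, where 4927 genes had an unadjusted p under 0.05, and 0 with 1 surrogate variable, where 2111 did. The surrogate variable partly followed the groups and was highest in stress replicate 2 (0.773), so fitting it can also remove part of the group difference. The count also depended on single libraries. No gene passed without control replicate 1, 2 or 4, or without stress replicate 1 or 4, whereas 36 passed without control replicate 3, 66 without stress replicate 2 and 26 without stress replicate 3. The number of genes at an unadjusted p under 0.05 stayed between 3526 and 5437 when any 1 library was left out.

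**Figure D2:**
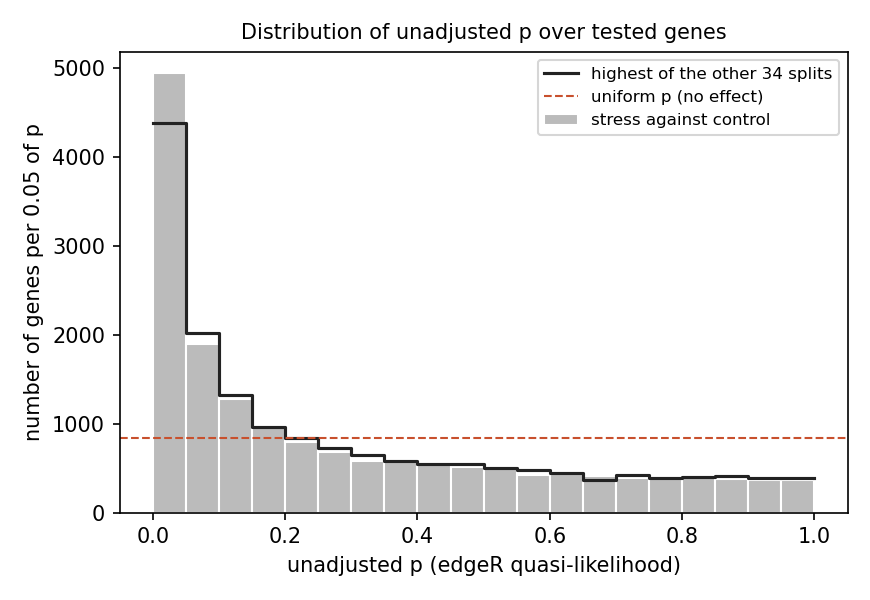
Number of tested genes in each interval of 0.05 of the unadjusted p from the edgeR quasi-likelihood test. Grey bars show stress against control, with 4939 genes in the first interval; the black line shows the highest of the other splits of the same 8 libraries into 4 and 4, with 4383; the dashed line is the 838 genes per interval expected with no difference.

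The gene with ID ENSRNOG00000051831 fell most among those that passed. Its level was 15.3 ± 2.79 CPM in control and 5.08 ± 1.27 CPM in stress rats (SD, n = 4 each), a log2 fold change of -1.59 (SE 0.18) and a 3.01-fold lower level, with an adjusted p of 0.0426 by edgeR's quasi-likelihood test. The lowest control rat had 12.4 CPM and the highest stress rat 6.61 CPM. ENSRNOG00000026036 fell from 15.1 ± 0.616 to 9.43 ± 0.983 CPM (SD, n = 4 each), a log2 fold change of -0.68 (SE 0.08, 1.599-fold lower), with the same adjusted p of 0.0426 in edgeR. The counts behind these levels were 244 to 812 per library for the first gene and 523 to 738 for the second. Both lost the threshold in edgeR on scaling by library size only (adjusted p = 0.0568 and 0.0654, log2 fold changes -1.55 and -0.64) and with 1 surrogate variable (adjusted p = 0.0749 for both, log2 fold changes -1.28 and -0.67). They also lost it without control replicate 1 (both 0.166), 2 (both 0.103) or 4 (0.0565 and 0.0803), and without stress replicate 1 (both 0.0642) or 4 (0.111 and 0.0502), with log2 fold changes of -1.49 to -1.68 for the first gene and -0.66 to -0.74 for the second. Over 23 alternatives each of the pair passed in 16, with adjusted p up to 0.166.

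No gene with a higher level under stress passed the threshold. The 2 with the smallest unadjusted p were ENSRNOG00000020344 and ENSRNOG00000010736. ENSRNOG00000020344 measured 28.9 ± 2.21 CPM in control and 47.1 ± 6.66 CPM in stress rats (SD, n = 4 each), a log2 fold change of 0.70 (SE 0.10) with an adjusted p of 0.0566 in edgeR. ENSRNOG00000010736 measured 12.02 ± 0.653 and 16.7 ± 1.06 CPM (SD, n = 4 each), a log2 fold change of 0.48 (SE 0.07) with the same adjusted p of 0.0566 in edgeR. For both, every stress rat lay above every control rat. Both passed in edgeR without stress replicate 2 (adjusted p = 0.0264 and 0.0474), without control replicate 3 (0.0282 and 0.0379) and without stress replicate 3 (0.00697 and 0.0463). Over 23 alternatives each passed in 8, with adjusted p up to 0.166.

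**Figure D3:**
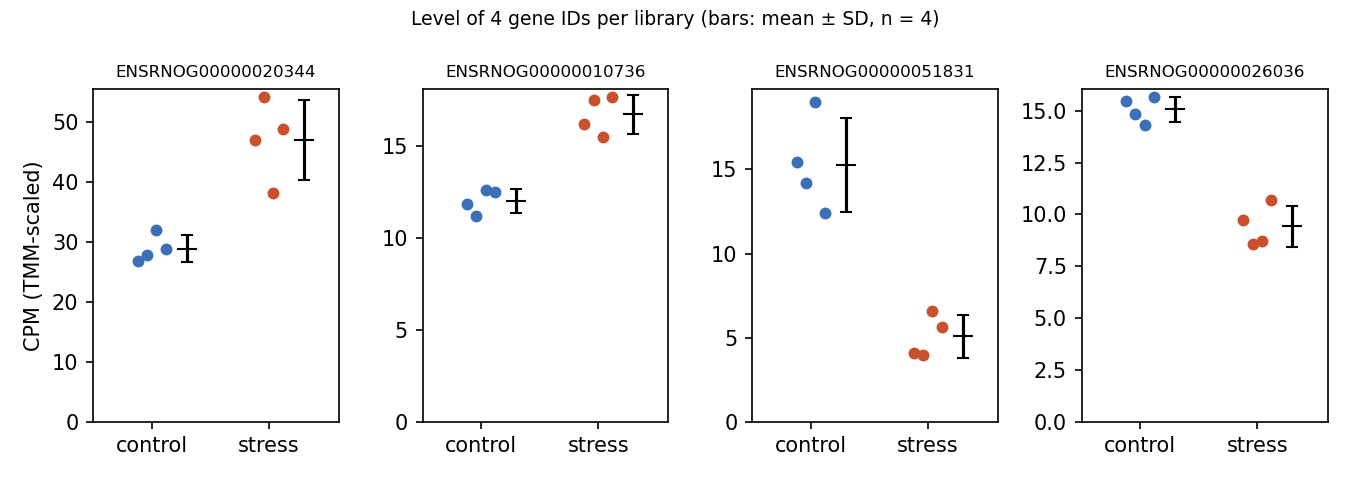
Levels in CPM of 4 gene IDs in each library, with control in blue and stress in orange; black bars give the mean ± SD over 4 rats, and each vertical axis starts at 0. The left pair, ENSRNOG00000020344 and ENSRNOG00000010736, was higher in every stress rat without passing the adjusted threshold, and the right pair, ENSRNOG00000051831 and ENSRNOG00000026036, was lower in every stress rat and passed it.

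With group as the only term, the share of increases among the small shifts was lower in tiers of higher level. Tested genes were divided by mean level into 3 tiers of nearly equal size. In the low tier (0.193 to 5.86 CPM), 607 genes at an unadjusted p under 0.05 were higher and 257 lower under stress, so 70.3% were higher. In the middle tier (5.86 to 35.8 CPM) 982 were higher and 714 lower (57.9% higher). In the high tier 1022 were higher and 1357 lower (43.0% higher). Scaling by library size only moved the higher share of all such genes from 52.9% to 70.2% and that of the high tier to 62.5%, so the direction in the high tier depends on the scaling, while the low tier stayed above 50% higher with each of the 4 scalings. The higher share of the low tier was 61.9% without control replicate 3. With 1 surrogate variable the order of the tiers changed, to 52.5% higher in the low, 62.1% in the middle and 44.6% in the high tier. Other splits of the same 8 libraries into 4 and 4 gave shares of one direction in the low tier of up to 77.8%. The split with 77.8% grouped control replicates 1, 3 and 4 with stress replicate 3, so it kept part of the group difference. A split that balanced the groups, control replicates 1 and 3 with stress replicates 1 and 3, gave 74.1%. A share as large as 70.3% thus also arose in a division that balanced the groups. Upper-quartile scaling gave 49.6% higher over all genes. No scaling moved the median log2 fold change of all genes by more than 0.04. The TMM factors did not overlap between the groups, at 0.972 to 1.002 in control and 1.008 to 1.026 in stress libraries (exact permutation p = 0.0286, adjusted p over 8 sample measures = 0.0457).

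Larger changes were more often increases than decreases with group as the only term. Whether other splits of the 8 libraries give such an excess was not examined. Of the genes at an unadjusted p under 0.05, 461 differed by 1.5-fold or more, 360 of them higher and 101 lower under stress, and 78 differed by 2-fold or more, 58 higher and 20 lower. Without stress replicate 2, 158 were higher and 95 lower by 1.5-fold or more, and 37 and 30 by 2-fold or more. With 1 surrogate variable, 117 were higher and 138 lower by 1.5-fold or more, and 45 and 45 by 2-fold or more. With only genes of at least 1 CPM in at least 4 libraries, the numbers were 195 and 46, and 14 and 8. With no filter they were 623 and 192, and 294 and 116. Without control replicate 3 they were 306 and 153, and 90 and 42. Leaving out each of the other libraries in turn gave 324 to 537 genes higher and 101 to 122 lower by 1.5-fold or more, and 62 to 114 higher and 26 to 36 lower by 2-fold or more. In 216 of the 461 genes, and in 36 of the 78, the groups did not overlap. The 3 largest increases, with log2 fold changes of 4.46, 4.33 and 3.60, each came from a single stress library (117.8 CPM in stress replicate 1, and 17.7 and 12.5 CPM in stress replicate 4), and none passed the adjusted threshold in edgeR.

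**Figure D4:**
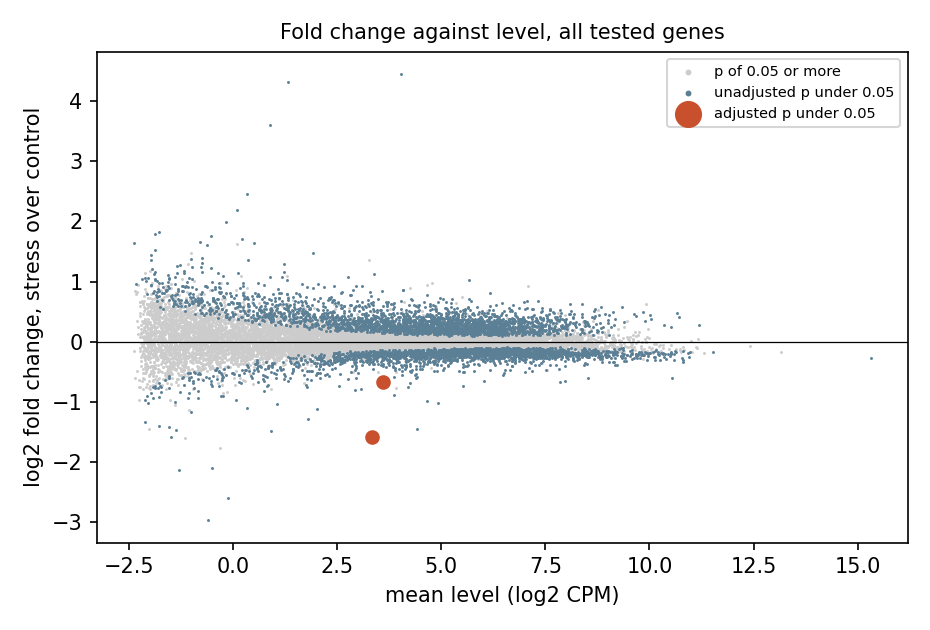
Log2 fold change of stress over control against mean level in log2 CPM for the 16760 tested genes. Grey points have an unadjusted p of 0.05 or more, blue points an unadjusted p under 0.05, and the 2 orange points an adjusted p under 0.05.

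More gene IDs had at least 1 read in the stress libraries, which were also deeper. The number was 20728 ± 180 in control and 21411 ± 134 in stress libraries (SD, n = 4 each, exact permutation p = 0.0286). After all libraries were thinned to the smallest total, the difference was smaller but the groups still did not overlap, at 20654 ± 134 and 20918 ± 129 IDs (SD, n = 4 each, exact permutation p = 0.0286, adjusted p over 8 sample measures = 0.0457). The thinned range was 20470 to 20779 in control and 20786 to 21086 in stress libraries. Only 1 random thinning was drawn, and another draw could close so small a gap.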

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

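4 gene IDs stood at 10 times or more the level of every other library in 1 library, with at least 1 CPM there, a limit chosen after the data were seen. All 4 cases lay in stress libraries and each inflated the group's fold change. In stress replicate 1, the ID with the largest fold change of the whole table stood at 117.784 CPM (7935 counts) against 0.982 to 1.69 CPM in the other 7 libraries, and another stood at 6.39758 CPM against 0.234 to 0.430 CPM. In stress replicate 4, a pair of IDs stood at 17.7495 CPM (990 counts) and 12.4784 CPM (696 counts), against at most 0.239 and 0.382 CPM elsewhere. For the last of these, the value of 0.381958 CPM in control replicate 1 was also set apart from the other controls. Each of these 5 values lay outside its group of 4 by more than the 95% critical value of Dixon's ratio of gap to range. Chance sets apart about 1 in 20 groups, 32 groups were examined, and these 4 IDs were included because of their single high library. None of the 4 passed the adjusted threshold in edgeR (adjusted p = 0.102 to 0.148), although all had an unadjusted p under 0.05.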

How the results depend on the processing

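The tests of thinning, of the newer quasi-likelihood estimate, of removing the 10 most abundant IDs and of an adjusted p under 0.06 were chosen after the data were seen. The 2 called genes, both lower, stayed 2 in number with DESeq2 size factors, upper-quartile factors, the stricter filter, limma-voom, the robust fit, the newer estimate, without the 10 most abundant IDs and with a fold of at least 1.5. Scaling by library size only and 1 surrogate variable gave 0 genes, and thinning gave 4, all lower. Other settings gave more: no filter 99 (61 higher, 38 lower), limma-voom with quality weights 404 (226, 178), the edgeR likelihood ratio test 1628 (1004, 624), DESeq2 2075 (1160, 915), an adjusted p under 0.06 27 (13, 14) and under 0.1 2349 (1314, 1035). The cause was not tested. In simulated counts with 200 of 16760 genes changed, DESeq2 made 19.7% false calls against 4.35% for the main test. These rates cannot be carried over to the real calls, since 52.1% of the real genes were estimated to differ. On the real data DESeq2 was also given all IDs, whereas the simulation held only the filtered genes. Leaving out 1 library gave 0 to 66 genes (0 to 34 higher, 0 to 32 lower). Genes at an unadjusted p under 0.05 stayed within 1.5 times of 4939 except with 1 surrogate variable (2111). The replicate block gave 697 genes (481 higher, 216 lower). The shared numbers showed no clear pairing of the rats: deviations of same-numbered libraries correlated at -0.05 to 0.19, and 3 of 8 libraries correlated best with their own number. With only 4 numbers to compare, a weak pairing cannot be excluded. No printed ID changed direction under any alternative. The corrections for GC content and length, the removal of named gene classes, and the 3 alternatives for gene lists were not run, 6 in all. With all libraries thinned to 42195741 counts, 4813 genes had an unadjusted p under 0.05, 4433 of them among the 4939.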

Other observations

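The tests of thinning and of the within-group axis, and the count of splits for the direction in the low tier, were set out before their results were seen. The fits without stress replicate 2, with 1 surrogate variable and with DESeq2 were fixed before the data were examined. Their use as tests of an explanation, the other counts of splits, and the tests of batch and of background were chosen after the result was seen, as was the thinning itself as an alternative.

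Whether 4939 genes with an unadjusted p under 0.05 exceed what any division of these rats would give was examined over all 35 splits into 4 and 4. Only 1 split, the real one, gave as many. The highest other gave 4383 genes and exchanges control replicate 4 with stress replicate 3, the neighbours on the first principal component; the median of the others was 430. The real split thus ranked first, the most that 35 splits can show, with a narrow margin over that split. As the count was also chosen after the result was seen, chance is made less likely for the broad shift but is not excluded. For the 2 genes past the adjusted threshold chance cannot be excluded either, since 2 of the 35 splits gave as many and the highest other gave 5. With DESeq2 the real split gave 2075 genes and the highest other, the same exchange, 1219.

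Several technical accounts of the broad shift were weighed. Unequal depth as such is argued against by thinning all libraries to the same total, where 4813 genes had an unadjusted p under 0.05. The same reads were used, so the 4433 of these genes that lie among the 4939 are no separate support. Thinning equalises counting only and cannot reach other differences that came with depth. Stress replicate 2 alone is argued against by the 3549 such genes found without it, where 840.8 are expected if no gene differed. The remaining libraries are in both fits, so the 3423 of these genes that lie among the 4939 are no separate support. Other splits of the remaining libraries were not examined. An axis of variation that also runs within the groups may account for part of it. Across genes, which are not independent replicates, the first axis of the within-group deviations correlated with the stress fold change at 0.447 in size. As much was given by 8 of 35 splits, the real one among them, and the highest other gave 0.576. The others of these 8 each differ from the real split by 1 exchange of libraries. Their within-group deviations hold part of the group difference, so the count is no measure of chance. The axis within controls alone gave 0.181 against 0.507 within stress libraries, and these 2 axes correlated at 0.319 in size. On the axis within stress libraries, stress replicate 2 scored 39.8 and the others -10.7 to 8.96. That library also enters the stress fold change. With 1 surrogate variable 2111 genes had an unadjusted p under 0.05, 1593 of them among the 4939, against 838 expected if no gene differed. That variable partly followed the groups, at -0.493 to 0.037 in control and -0.124 to 0.773 in stress libraries. Part of the fall from 4939 may therefore be group difference taken up by the variable. Of the 35 splits fitted with 1 surrogate variable each, the highest other gave 2005 and the median of the others was 726. The limit for excluding this axis as the whole cause, more than 1.5 times every other split, was set after the result was seen and was not reached, so the axis stays open as the whole cause. A library or sequencing batch that followed the groups cannot be told apart from stress, since the shallowest stress library was 5414387 counts deeper than the deepest control, and an effect of stress itself remains untested beside it.

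The excess of higher genes in the low tier was set against other splits. The larger share of one direction there was 70.3% in the real split, and 6 of 35 splits, the real one among them, gave as much or more, up to 77.8%. Most of the others differ from the real split by 1 exchange of libraries and keep part of the group difference, so their count is no measure of chance. The split of control replicates 1 and 3 with stress replicates 1 and 3, which balances the groups, gave 74.1%. Chance can therefore not be excluded for the excess. Unequal depth as such is argued against, since 69.1% were higher after thinning. A background of reads spread over all IDs, such as unspliced or genomic sequence, was weighed by the rarest IDs. The 6178 IDs below a mean of 0.1 CPM summed to 149.96 ± 12.4 CPM in control and 171.7 ± 17.5 CPM in stress libraries (SD, n = 4 each, exact permutation p = 0.0857). The lowest stress library lay below the highest control library, with a difference of -4.12 CPM. As the stress mean was still the higher, this comparison did not decide the question. The mean excess of 21.8 CPM was shared by all 6178 IDs, while each low-tier gene averaged at least 0.193 CPM. Low-tier genes at an unadjusted p under 0.05 changed by a median of 0.526 in log2. These sizes argue against an equal background on each ID as the cause. A background that differs between genes stays possible.

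At equal depth, 19 IDs had a read in all 4 stress libraries and in no control library, and 6 had the reverse. At full depth the numbers were 40 and 4, and none of these IDs averaged more than 4.5 counts per library in the group that had them.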
